A study of Mus musculus with 9 samples.

How the data were processed

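Bulk RNA sequencing of total RNA, extracted with TRIzol and described in the labels as sequencing of long noncoding RNA, was deposited for mouse seminal vesicle at 3, 13 and 21 months, with 3 libraries per age. The labels do not say whether the replicates are separate animals. The deposited table holds raw read counts per Ensembl gene, made by the authors, per the labels, with HISAT2 and featureCounts on GRCm38 (mm10), with no normalization. The tool versions, gene annotation, strand setting and treatment of reads that map to several places are not given, so that overlapping genes and near-identical paralogs cannot be separated here. All 9 columns hold whole numbers and were assigned to ages by their names. Symbols and coordinates were taken from the GENCODE mouse release M21 annotation by Ensembl identifier. Of 53379 identifiers 53274 were matched, and the other 105 held 0.0084% of the counts.

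Genes were kept with filterByExpr of edgeR 4.0.16 by age (minimum count 10, minimum total 15), which left 16067 genes and set 37312 aside. Library sizes were scaled by TMM. A negative binomial model with 1 coefficient per age was fitted to all 9 libraries, and ages were compared with the edgeR quasi-likelihood F test in R 4.3.3 (residual degrees of freedom 6, prior degrees of freedom 3.63). The p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Positive log2 fold changes are higher at the older age. SE is the absolute log2 fold change divided by the square root of F. CPM (counts relative to the library size, per 1e+06) is scaled by TMM where a mean over an age is given, and by the library total where a value of a single library is given. The mean TMM factor was 0.8625 ± 0.0102, 0.9019 ± 0.0866 and 1.318 ± 0.3296 at 3, 13 and 21 months (SD, n = 3). Scaling by library totals alone moved the median log2 fold change of all genes by 0.064 at 13 against 3 months, 0.609 at 21 against 3 months and 0.548 at 21 against 13 months, and changes are given relative to TMM.

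A total of 45 gene lists, 27 of pathways and 18 of cell types, was fixed with the tests, the comparisons, the naming rule and most alternatives before the data were examined. Of these, 41 lists with at least 4 tested genes were tested as sets with camera of limma 3.58.1 (preset correlation 0.01, prior count 2), adjusted over all lists within a comparison, then with an estimated correlation and with fry. Named genes are the 8 with the largest change in each direction among called genes whose 3 libraries at each age do not overlap, with an average log2 CPM of at least 1 and no predicted or clone name, up to 4 called members of each list, the 10 most abundant genes, and a few genes fixed by name, among them Cdkn2a, Cdkn1a and Mki67. Some genes that the rule or another selection picks are not reported here. A called list without a called member gives its 2 genes of smallest p as values. Shares of counts were compared by exact two-sided permutation tests, and intervals of single shares are 95% Wilson intervals. Depth sets a floor of 3 counts, or 0.121 to 0.1814 CPM in 1 library.

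The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals alone, TMM without the 50 most abundant genes, 2 other low-count filters, only the 6 libraries of the 2 ages compared, a replicate block, a 2-fold minimum and leaving out each library. Added after seeing the data were a robust spread and 21 months as replicate 3 alone, where the lone library is assumed to vary like the other ages. The same steps were tested on simulated data with 200 changed genes, drawn from genes above a minimum total count, beside a planted list. They recovered 55.8%, 46.9% and 44.8% of 2-fold changes at 13 against 3, 21 against 3 and 21 against 13 months. They recovered 86.7%, 85.6% and 87.6% of 4-fold changes, with 6.5%, 7.6% and 6.4% false calls. All simulated libraries started from the 3-month means, without the prostate and fat transcripts found in 21-month replicates 1 and 2. Recovery with the real 21-month libraries may therefore differ. Splicing, isoforms and reads outside annotated genes were not analysed here.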

Results

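RNA of the seminal vesicle, the male accessory gland that makes much of the seminal fluid, was sequenced from mice at 3 ages. There were 3 libraries at 3 months, 3 at 13 months and 3 at 21 months, 9 in all. The total count per library, in the order of replicates 1 to 3, was 20180174, 16536160 and 16608835 at 3 months. It was 20761662, 19415757 and 24791943 at 13 months, and 17137206, 20804323 and 22523316 at 21 months. The table held 53379 genes, of which 23609 had no count in any library and 16067 had enough counts to be tested. In a principal component analysis of log2 CPM, the first component held 41.3% of the variance and the second 18%. On the first component 21-month replicates 1 and 2 lay at 61.02 and 63.79, far from 21-month replicate 3 at 5.30 and from the other 6 libraries. The biological coefficient of variation was 22.4%. The series title asks which features of the seminal vesicle transcriptome change with age.

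Transcripts of the secreted seminal vesicle proteins made up most of the RNA counted at 3 and 13 months. The list of secretory proteins took 61.9% ± 1.21 of counts at 3 months (SD, n = 3), 62.2% ± 2.94 at 13 months and 42.7% ± 18.1 at 21 months. Svs5 (ENSMUSG00000017004, GRCm38 chromosome 2, 164332740 to 164334396), the transcript of highest mean abundance over the 9 libraries, alone took 16.7% ± 1.40, 17.3% ± 1.20 and 12.8% ± 5.29. At 21 months the secretory share was 23.05% in replicate 1 (95% Wilson interval 23.03 to 23.07), 46.56% in replicate 2 (46.54 to 46.58) and 58.59% in replicate 3 (58.57 to 58.61). The difference from 3 months gave p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 libraries allow, and 0.24 after adjustment over 12 such tests. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

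Replicates 1 and 2 at 21 months carried transcripts that the other 7 libraries held at much lower levels. In replicate 1 the list of prostate epithelium genes took 2.601% of counts (95% Wilson interval 2.593 to 2.609), against a mean of 0.0152% ± 0.00170 at 3 months (SD, n = 3). Tgm4, a prostate transglutaminase, reached 17560 CPM there and Pbsn, the gene of probasin, 6317, and the highest value of either in another library was 0.524. The gene 9530053A07Rik (chromosome 7, 28129466 to 28164811), chosen after its values were seen, took 8.91% of that library (95% Wilson interval 8.894 to 8.921) and under 0.001% of each other library. In replicate 2 the adipocyte list took 0.391% of counts (95% Wilson interval 0.3881 to 0.3934), and in replicate 1 0.0568% (0.05567 to 0.05792). In replicate 3 it took 0.00254% (0.002344 to 0.002761). Fabp4, the fatty acid binding protein of fat cells, stood at 78.19, 779.07 and 1.07 CPM in 21-month replicates 1, 2 and 3. Some nerve genes, chosen after their values were seen, were higher in replicates 1 and 2 as well. Snap25 stood at 1.225 and 9.277 CPM there and at 0 in each other library, and Tubb3 at 1.984 and 11.248, against 0.311 in the highest other. The markers of nerve and Schwann cells at 21 against 13 months had a median of 1.09 (adjusted p = 0.0196, or adjusted p = 0.399 with an estimated correlation). It was 0.54 (0.0841) without 21-month replicate 2 and 0.16 (0.707) with replicate 3 alone, and leaving out any 1 library of 3 or 13 months or 21-month replicate 3 raised it to between 1.80 and 3.09. The call also ended with library totals alone and with at least 10 counts in all 9 libraries. Each comparison with 21 months is therefore given below also with replicate 3 as the only 21-month library, an alternative chosen after seeing the data.

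**Figure D1:**
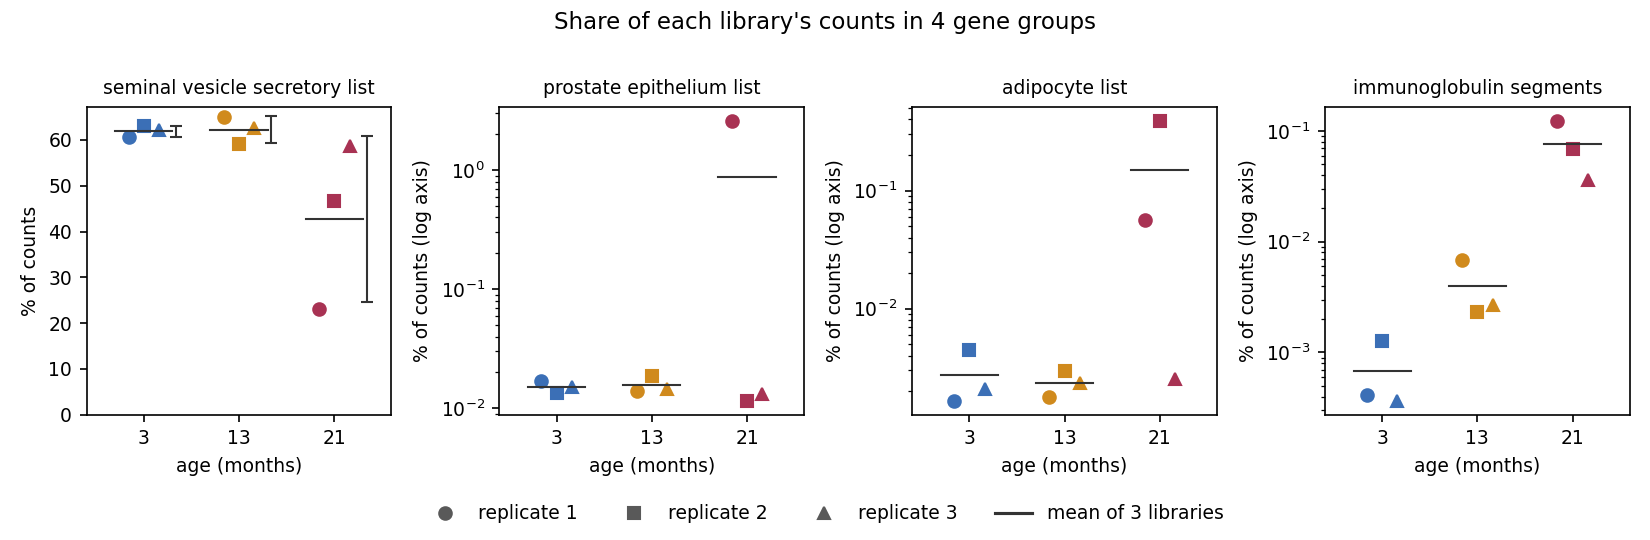
Share of each library's counts, in percent, taken by 4 gene groups at 3, 13 and 21 months, with libraries as points, means of 3 libraries as lines and 1 SD as bars in the secretory panel, and log axes in the other 3. The secretory share of 21-month replicate 1 is 23.05%, its prostate share is 2.601%, and the adipocyte share of 21-month replicate 2 is 0.391%.

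Between 3 and 13 months, genes of dividing cells fell and few genes rose. Of 16067 genes tested, 66 were lower and 7 higher at 13 months at an adjusted p under 0.05. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), the gene of the proliferation antigen Ki-67, fell from 51.2 ± 6.17 to 6.35 ± 2.96 TMM-scaled CPM (SD, n = 3). Its log2 fold change was -3.02 ± 0.33 (SE), with an adjusted p of 0.00914, and each 13-month library lay below each 3-month library. Nusap1, of the mitotic spindle, fell by 3.04 on the log2 scale (adjusted p = 0.00550), Cenpf, of the kinetochore, by 3.04 (0.00987), Tpx2, a spindle assembly factor, by 2.88 (0.0144) and Top2a, DNA topoisomerase II alpha, by 2.87 (0.0230). Of the 40 tested genes of the cell proliferation list, 18 fell and 0 rose, or 33 and 0 when adjusted over the list alone. The list's median log2 fold change was -1.92. Its adjusted p was 2.48e-51 by camera with a preset correlation, 0.0472 with an estimated correlation and 0.00182 by fry, and it was the only list called by all 3. The cyclin genes Ccna2 (-2.65 ± 0.39, adjusted p = 0.0221) and Ccnb1 (-3.80 ± 0.41, 0.00914), the spindle gene Aspm (-2.62 ± 0.28, 0.00914) and Ube2c (-3.12 ± 0.34, 0.00914), a ubiquitin-conjugating enzyme of mitotic exit, also fell. Brca1, a DNA repair gene, fell by 1.96 (adjusted p = 0.0391) and was the only called gene of the 32 in the list of p53 targets and DNA damage response. The call of Brca1 ended with limma-voom, with a replicate block and with library totals alone.

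**Figure D2:**
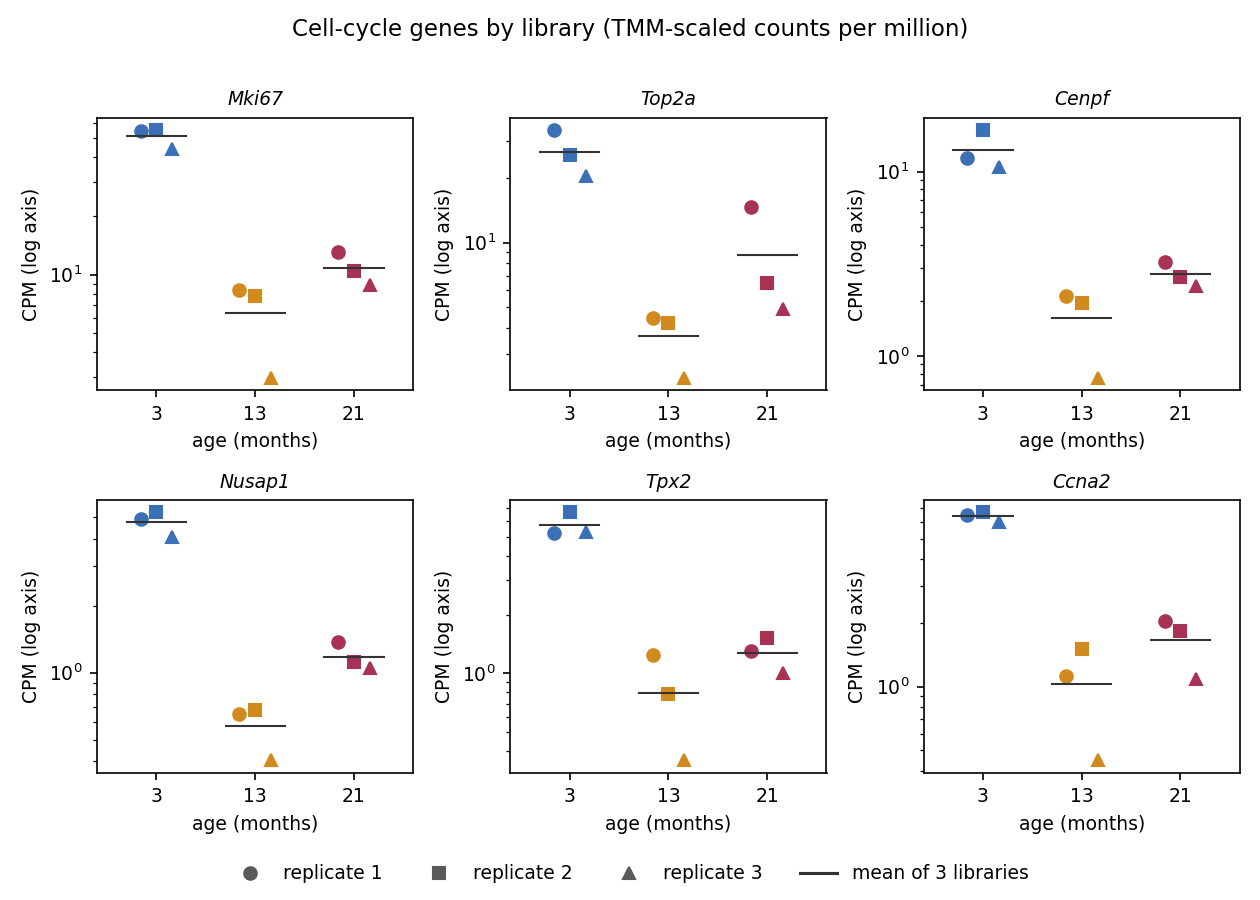
TMM-scaled CPM, on log axes, of 6 cell-cycle genes at 3, 13 and 21 months, with libraries as points and means of 3 libraries as lines. Mki67 averages 51.2 at 3 months, 6.35 at 13 months and 10.8 at 21 months, and each older library lies below each 3-month library.

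By 13 months Amy1, Fgf10, Il7r, Creb3l1 and Cpeb2 rose, and Neb, Wfdc15b and Krt14 fell. With all libraries kept, limma-voom ended the calls of Amy1, Fgf10, Il7r and Krt14, and a replicate block those of Fgf10, Il7r and Creb3l1. Library totals alone ended those of Il7r, Creb3l1 and Krt14, and at least 10 counts in all 9 libraries that of Krt14. Amy1 (ENSMUSG00000074264, chromosome 3, 113555710 to 113606699), a salivary-type amylase, rose from 4.26 ± 0.748 to 67.7 ± 37.9 CPM (log2 3.99 ± 0.49, adjusted p = 0.0126). Fgf10 (chromosome 13, 118669791 to 118792115), a growth factor made by mesenchyme, rose from 3.54 ± 0.855 to 38.2 ± 15.8 (log2 3.43 ± 0.53, adjusted p = 0.0259). A noncoding gene annotated on the opposite strand, Gm16263, overlaps Fgf10, and the strand setting of the counts is not given. Il7r, the interleukin 7 receptor, rose by 2.06 ± 0.35 (adjusted p = 0.0440), Creb3l1, a transcription factor of the secretory pathway, by 1.77 ± 0.25 (0.0207) and Cpeb2, an RNA-binding translational regulator, by 1.11 ± 0.15 (0.0194). Neb (ENSMUSG00000026950, chromosome 2, 52136647 to 52378474), the gene of the muscle protein nebulin, fell from 210.5 ± 35.1 to 33.0 ± 13.2 CPM (log2 -2.67 ± 0.34, adjusted p = 0.0142). The other 7 tested skeletal muscle markers were not called. Wfdc15b, a protease inhibitor gene, was the 1 gene of 16 tested secretory protein genes that fell (-1.18 ± 0.14, adjusted p = 0.0126). That list had a median of -0.08, with adjusted p = 0.372. Krt14, a keratin of basal cells, was the 1 of 9 basal epithelium markers that fell (-0.94 ± 0.16, adjusted p = 0.0400), or 1 of 3 when adjusted over the list alone. The basal list had a median of -0.58, with adjusted p = 6.07e-05, and 0.54 with an estimated correlation. Of 22 T and NK cell markers none passed over all genes and 6 rose when adjusted over the list alone, with a median of 1.28 and adjusted p = 5.69e-11, or 0.54 with an estimated correlation. For the list: markers of T and NK cells, 13 against 3 months, the median was 0.81 without 13-month replicate 2. Of 16 plasma cell markers 3 rose over the list alone, with a median of 2.36, or 1.63 with genes absent at 3 months at their bound, and adjusted p = 1.82e-05, or 0.54 with an estimated correlation. The median of the markers of plasma cells and immunoglobulins at 13 against 3 months was 0.27 with at least 10 counts in all 9 libraries, where the call ended (adjusted p = 0.0906), 0.37 with only the 6 libraries of these ages and 1.51 without 13-month replicate 1. The lists of fibroblasts and of matrix were lower with no single gene called, while smooth muscle markers had a median of 0.27 and were not called (adjusted p = 0.0869 by camera). The markers of fibroblasts at 13 against 3 months had a median of -0.51 (adjusted p = 8.59e-04, or 0.802 with an estimated correlation), with 1 of 14 positive, and the 44 genes of collagens and extracellular matrix one of -0.21 (0.00160, or 0.830 with an estimated correlation). Without 13-month replicate 1 both calls ended, at -0.29 (adjusted p = 0.114) and -0.0072 (0.447), and without 13-month replicates 2 and 3 the median of collagens and extracellular matrix was -0.41 and -0.43.

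The number of genes changed between 3 and 13 months rested on all 6 libraries compared. Without 3-month replicates 1, 2 and 3 they were 4, 1 and 9 genes, without 13-month replicates 1, 2 and 3 they were 20, 7 and 11, and without 21-month replicate 1, which shares the estimate of the spread, 150. With 21-month replicate 3 as the only library of its age 229 genes were called, 60 higher and 169 lower, among them all 73. Each of the 18 named genes called here lost its call without at least 1 library. With the preset correlation the cell proliferation list was called at all of these settings, with medians from -2.08 to -1.38 over its 18 alternatives. With an estimated correlation its adjusted p was 0.163 without 21-month replicate 1, 0.131 without 21-month replicate 2 and 0.361 with 21-month replicate 3 alone, so that this call ended.

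Between 3 and 21 months, immunoglobulin transcripts and some genes of immune cells rose and some genes of dividing cells fell. Of 16067 genes tested, 202 were higher and 123 lower at 21 months. Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), the constant segment of the IgM heavy chain, rose from 5.06 ± 3.71 to 285 ± 126 CPM (SD, n = 3; log2 5.82 ± 0.69, adjusted p = 0.0153). Igkc (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), the kappa light chain constant segment, rose from 1.08 ± 1.10 to 130.5 ± 53.2 (log2 6.94 ± 0.74, adjusted p = 0.00988). Jchain, which joins IgM and IgA polymers, rose by 5.94 ± 0.69 (adjusted p = 0.0153) and Igha, the IgA heavy chain segment, by 4.89 ± 0.81 (0.0297). Ighg2b, Igkv3-2 and Iglc2 had no count at 3 months. They were at least 202-fold, 168-fold and 37.0-fold higher at 21 months, measured against a floor of 3 counts over the 3 libraries of the group. Their adjusted p was 0.0426, 0.0376 and 0.0162. The calls of Igha, Ighg2b and Igkv3-2 ended with limma-voom. That of Ighg2b also ended with a robust spread and with only the 6 libraries compared. Of the 27 tested immunoglobulin segments, 14 rose and 0 fell. Segments absent or nearly absent at 3 months pass the filter only through older libraries, so that a fall could hardly be seen. Together the segments took 0.000416%, 0.00128% and 0.000367% of counts at 3 months, 0.00679%, 0.00233% and 0.00271% at 13 months, and 0.124%, 0.0693% and 0.0358% at 21 months. Of the 16 tested plasma cell markers 7 rose, 11 when adjusted over the list alone. Their median was 5.75, or 5.45 with genes absent at 3 months set at their bound, with adjusted p = 1.02e-08, 0.322 with an estimated correlation and 0.00522 by fry. With 21-month replicate 3 alone that median was 5.90. With at least 10 counts in all 9 libraries, a filter that keeps 6 of the 16 and removes genes absent at 3 months, the median of the markers of plasma cells and immunoglobulins at 21 against 3 months was 0.29 (adjusted p = 0.604) and the call ended. Haemoglobin genes, of red blood cells, took 0.0047% ± 0.0021 of counts at 3 months and 0.0106% ± 0.0071 at 21 months (exact permutation p = 0.2, adjusted 0.4).

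**Figure D3:**
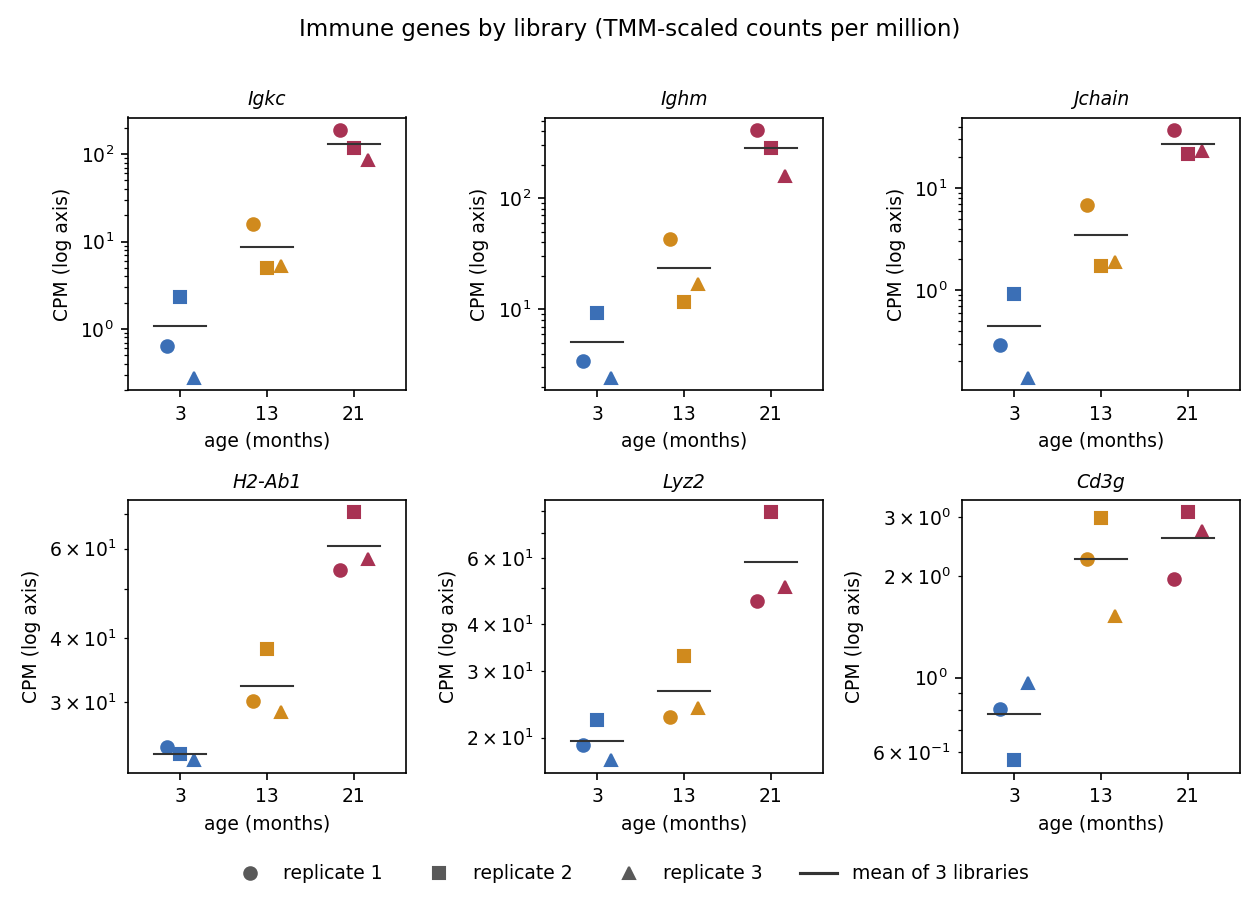
TMM-scaled CPM, on log axes, of 6 immune genes at 3, 13 and 21 months, with libraries as points and means of 3 libraries as lines. Each 21-month library lies above each 3-month library, with means of 1.08 and 130.5 for Igkc and 23.8 and 60.7 for H2-Ab1.

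Some genes of antigen presentation, complement, macrophages and T cells were called higher at 21 months as well. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), an MHC class II chain, rose from 23.8 ± 0.745 to 60.7 ± 8.68 CPM (log2 1.35 ± 0.14, adjusted p = 0.00988). H2-Eb1 rose by 1.16 ± 0.17, Cd74, the invariant chain, by 1.15 ± 0.18 and Ctss, the cathepsin that cleaves it, by 1.21 ± 0.17. In the MHC class II list 5 of 10 genes rose, all 10 when adjusted over the list alone (median 1.18, adjusted p = 0.397 with an estimated correlation). In the complement list 5 of 20 rose, 13 over the list alone (median 0.98, adjusted p = 0.440 with an estimated correlation), among them C4b (2.75 ± 0.54), C1qa (1.08 ± 0.20) and C1qc (1.21 ± 0.23). Of 20 macrophage and monocyte markers 3 rose, 18 over the list alone (median 1.11, adjusted p = 0.397 with an estimated correlation), with Lyz2, of lysozyme, up 1.58 ± 0.23 and Adgre1, of F4/80, up 1.51 ± 0.31. Of 22 T and NK cell markers 4 rose, 16 over the list alone (median 1.74, adjusted p = 0.397 with an estimated correlation), with Cd2 up 2.99 ± 0.57 and Cd3g up 1.72 ± 0.34. The B cell receptor gene Cd22 rose by 4.54 ± 0.96 (adjusted p = 0.0490). The B cell gene Ms4a1 was too sparse to test, with 97, 27 and 3 counts in 21-month replicates 1, 2 and 3. In the chemokine and cytokine list 3 of 22 rose, 11 over the list alone (median 0.97, adjusted p = 0.322 with an estimated correlation): the chemokines Ccl8 (3.89 ± 0.48) and Cxcl13 (3.45 ± 0.49) and the cytokine Il18 (2.19 ± 0.46). The calls of Cd74, C4b, C1qa, C1qc, Cd2, Cd3g, Cd22 and Il18 ended with 21-month replicate 3 alone, while H2-Ab1, H2-Eb1, Ctss, Lyz2, Adgre1, Ccl8 and Cxcl13 kept theirs. The medians were then 0.90 for MHC class II, 0.47 for complement, 0.77 for macrophages, 1.18 for T and NK cells and 0.42 for chemokines and cytokines. The call of Adgre1 (adjusted p = 0.047) ended under 11 of its 20 alternatives. Among these were limma-voom, a replicate block, at least 10 counts in all 9 libraries and only the 6 libraries compared. The last also ended the call of H2-Eb1. Over all alternatives the lowest log2 fold changes were 0.92 for Cd74, 1.35 for C4b, 0.85 for C1qa and 0.91 for C1qc. They were 2.23 for Cd2, 1.54 for Cd3g, 2.55 for Cd22 and 1.43 for Il18. For the list: chemokines and inflammatory cytokines, 21 against 3 months, the median was 1.54 without 21-month replicate 3 and 1.499 without 3-month replicate 2.

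Single genes of matrix, stress response and lysosome rose as well. Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), of the matrix protein thrombospondin 1, rose from 11.3 ± 2.55 to 52.0 ± 3.604 CPM (log2 2.21 ± 0.19, adjusted p = 0.00557). It was the 1 of 44 collagen and matrix genes called. For the list: collagens and extracellular matrix, 21 against 3 months, the median was 0.48 (adjusted p = 0.0705), 0.072 (0.775) without 21-month replicate 2 and 0.16 (0.502) with replicate 3 alone. The list was called without 21-month replicate 1, at 0.58 (7.03e-04, or adjusted p = 0.623 with an estimated correlation), and with a replicate block (0.0148). The call of Thbs1 ended without 3-month replicate 3 (adjusted p = 0.0585, the highest over its 20 alternatives). Over these alternatives the log2 fold change of Thbs1 ran from 2.02 to 2.83. Timp1, an inhibitor of matrix proteases, fell by 2.25 (adjusted p = 0.0426). In the senescence list 2 of 22 genes rose, Cdkn1a among them, with a median of 0.35 and adjusted p = 0.0353, or 0.604 with an estimated correlation. For the list: senescence-associated genes, 21 against 3 months, the median was 0.56 without 21-month replicate 1 and 0.19 without 21-month replicate 2, where the call ended (adjusted p = 0.234). It also ended without 21-month replicate 3 (0.0585), with only the 6 libraries compared (0.0619), with at least 10 counts in all 9 libraries (0.106) and with library totals alone (0.0815). Cdkn1a, of the cell cycle inhibitor p21, rose by 2.01 ± 0.43 (adjusted p = 0.0497). Cdkn2a was too sparse to test, with 4, 2 and 1 counts at 3 months, 35, 4 and 0 at 13 months and 4, 4 and 14 at 21 months. Among immediate-early genes Ccn1 and Socs3 rose, 2 of 22 or 12 over the list alone (median 0.66, adjusted p = 0.440 with an estimated correlation). The lysosomal genes Ctsh (1.19 ± 0.14) and Gaa (0.62 ± 0.11) were among 3 of 38 that rose in a list with a median of -0.0040 and adjusted p = 0.995. Gpx3, a secreted glutathione peroxidase, rose by 2.10 ± 0.39 and Gclc, which makes the first step of glutathione synthesis, fell by 0.88 (adjusted p = 0.0400 and 0.0497). Snhg11, a small nucleolar RNA host gene that the annotation types as protein coding (5.40 ± 1.05), and Ptprz1, a receptor phosphatase (4.42 ± 0.90), rose with wide spreads between the 21-month libraries, at 6.70 ± 6.47 and 8.96 ± 9.86 CPM. The calls of Timp1, Cdkn1a, Ccn1, Socs3, Gaa, Gpx3, Gclc, Snhg11 and Ptprz1 ended with 21-month replicate 3 alone, and also without 21-month replicate 2. With replicate 3 alone the log2 fold change was 0.96 for Gpx3, 1.29 for Cdkn1a, 2.59 for Snhg11 and 2.65 for Ptprz1, and the call of Ctsh ended too.

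Among genes that fell, Mki67 was 10.8 ± 2.12 CPM at 21 months (log2 -2.25 ± 0.32, adjusted p = 0.0202). Cenpf fell by 2.23, Tpx2 by 2.16 and Cdk1, the mitotic kinase, by 2.10. Of the 40 proliferation genes 16 fell, 30 over the list alone (median -1.31, adjusted p = 2.27e-21, 0.322 with an estimated correlation and 0.00522 by fry), and with 21-month replicate 3 alone the median was -1.77. Gdpd2 (ENSMUSG00000019359, chromosome X, 100729873 to 100738895), a glycerophosphodiester phosphodiesterase, fell from 11.8 ± 3.35 to 0.709 ± 0.271 CPM (log2 -4.03 ± 0.51, adjusted p = 0.0161). Dgat2l6, of a family of acyltransferases, fell by 2.599 (adjusted p = 0.0272) and Neb by 3.08 (0.0141). Trpv6, a calcium channel of secretory epithelia that is also in the prostate list, fell by 1.60 (0.0426). Among the secretory proteins Wfdc15b fell by 1.55 (adjusted p = 0.00656) and was the 1 of 16 called (median -1.03, adjusted p = 1.46e-06, or 0.529 with an estimated correlation, and -0.30 with 21-month replicate 3 alone). For the list: seminal vesicle secretory proteins, 21 against 3 months, the median was -0.63 without 21-month replicate 1 and -1.60 without 21-month replicate 3. Cenpf, Tpx2, Gdpd2 and Trpv6 lost their calls with 21-month replicate 3 alone, while Mki67, Cdk1, Dgat2l6, Neb and Wfdc15b kept theirs. Over all alternatives the smallest falls were -1.595 for Cenpf, -1.537 for Tpx2, -3.45 for Gdpd2 and -0.93 for Trpv6. The 10 most abundant genes, all in the secretory protein list, had log2 fold changes from -1.24 for Svs6 to -0.83 for Svs5. They were not called, with adjusted p from 0.199 to 0.429. Of 53 androgen-responsive genes none passed over all genes, while 7 rose and 5 fell when adjusted over the list alone, and the list was not called (median 0.06, adjusted p = 0.7997).

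The number of genes changed between 3 and 21 months moved with single libraries, least without 21-month replicate 1, where it was 471. Without 3-month replicates 1, 2 and 3 they were 2, 4 and 0 genes in edgeR, the last with 3298 genes at an unadjusted p under 0.05. Without 13-month replicates 1, 2 and 3 they were 135, 115 and 159, and without 21-month replicates 2 and 3 they were 48 and 2349. With 21-month replicate 3 alone 57 genes were called, 38 higher and 19 lower, 38 of them among the 325, and 22 of the 58 named genes kept their call. Each of the 58 named genes called here lost its call without at least 1 library. In the full fit 3923 genes had an unadjusted p under 0.05, where chance gives 803.

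Between 13 and 21 months Thbs1 was the 1 gene of 16067 called by edgeR, while DESeq2 called 428 and limma-voom 3. Thbs1 rose from 12.1 ± 2.54 to 52.0 ± 3.604 CPM (SD, n = 3; log2 2.10 ± 0.19, adjusted p = 0.0159). An unadjusted p under 0.05 was reached by 2525 genes, where chance gives 803. Igkc (3.92 ± 0.60), Iglc2 (5.01 ± 0.58), H2-Ab1 (0.91 ± 0.14), C3 (1.66 ± 0.29), Cxcl13 (2.57 ± 0.44) and Lyz2 (1.14 ± 0.22) had positive log2 differences that did not pass, each with adjusted p = 0.197. Adjusted over the list alone, 9 of 16 plasma cell markers rose and 1 fell (median 2.28, adjusted p = 0.373 with an estimated correlation). In the same way 9 of 10 MHC class II genes rose (median 0.77, adjusted p = 0.373 with an estimated correlation), as did 11 of 20 complement genes (median 0.92, 0.373) and 4 of 14 fibroblast markers (median 0.84, 0.387). All 9 tested adipocyte markers rose over the list alone (median 9.52, adjusted p = 0.387 with an estimated correlation), and the median was -0.59 with 21-month replicate 3 alone, against the adipocyte share of replicates 1 and 2 given above. With 21-month replicate 3 alone the medians were 2.67 for plasma cells, 0.45 for MHC class II, 0.53 for complement and 0.41 for fibroblasts, and without 21-month replicate 2 they were 0.56 for complement and 0.38 for fibroblasts. Mki67 was 0.77 ± 0.32 higher on the log2 scale at 21 than at 13 months without passing (adjusted p = 0.297). The call of Thbs1 ended without 3-month replicate 3, without 13-month replicates 1 and 2 and without 21-month replicate 2, each of which left 0 genes called in edgeR. Those fits gave 2297, 1595, 2571 and 1815 genes changed between 13 and 21 months at an unadjusted p under 0.05. Leaving out 21-month replicate 3 gave 1244 genes called at an adjusted p under 0.05. With 21-month replicate 3 alone Thbs1 had a log2 fold change of 1.99 and an adjusted p of 0.0515, in a range up to 0.139 over its 20 alternatives, and the 1 gene then called was another.

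The genes changed across the 3 ages, in a test of any difference among them, numbered 144. The count was 4, 3 and 3 without 3-month replicates 1, 2 and 3, 62, 61 and 46 without 13-month replicates 1, 2 and 3, and 315, 93 and 1639 without 21-month replicates 1, 2 and 3. Both older ages shared 54 called genes against 3 months, 5 higher and 49 lower, where independent lists of these sizes would share 0.088 and 0.505. The genes higher at both ages were Amy1 (log2 3.98 ± 0.49 at 21 months), Creb3l1 (2.39 ± 0.24), Il7r (2.65 ± 0.34), Fgf10 (2.62 ± 0.52) and Gm16263 (2.44), the last chosen after its values were seen. Mki67, Nusap1, Cenpf, Tpx2, Neb and Wfdc15b were among those lower at both. Both comparisons use the same 3-month libraries, which makes their errors alike. In 20 simulations of unchanged groups all 9 libraries were drawn from a common mean per gene. Both comparisons then shared the drawn 3-month libraries. With no gene changed, 0 genes were called in both. That count cannot say whether 54 exceeds what shared 3-month libraries give between ages that do change. The covariance of the fitted log2 fold changes across genes was 0.197, against 0.061 in the simulations (0.056 to 0.066), an excess of 0.136. The correlation across genes, which are not independent replicates, was 0.548 and lay within the simulated range of 0.498 to 0.559. With 3 control libraries the controls could not be split. Without 3-month replicates 1, 2 and 3 the number shared was 1, 1 and 0. It was 18, 7 and 11 without 13-month replicates 1, 2 and 3, and 90 and 22 without 21-month replicates 1 and 2.

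Of 41 lists tested as sets, 12 were called at 13 against 3 months, 19 at 21 against 3 months and 24 at 21 against 13 months with the preset correlation, and 1, 0 and 0 with an estimated correlation. Without 3-month replicate 1 the first of these was 7. With the preset correlation 13 lists were called in no comparison, and 8 of them, among these androgen-responsive genes, the polyol pathway, ion and fluid transport, and lysosome and autophagy, under no alternative scaling, filter or set of libraries. The other 5, which include the unfolded protein response, smooth muscle markers and circadian clock genes, were called under some. For the list: unfolded protein response and ER chaperones, 21 against 3 months, the median was -0.05 (adjusted p = 0.0998). It was -0.44 without 21-month replicate 1 (1.18e-06, or adjusted p = 0.479 with an estimated correlation), -0.13 without 3-month replicate 2 (0.0278) and -0.24 with 21-month replicate 3 alone (0.00307, or adjusted p = 0.770 with an estimated correlation). It was not called at 0.12 without 21-month replicate 2, -0.0031 without 21-month replicate 3, 0.053 without 3-month replicate 1 and -0.11 without 3-month replicate 3. For the list: markers of smooth muscle, 21 against 3 months, the median was 0.30 (0.0792), 0.47 without 21-month replicate 1 (0.00814, or adjusted p = 0.623 with an estimated correlation) and 0.29 without 13-month replicate 1 (0.0470). It was 0.079 without 21-month replicate 2 and 0.20 without 3-month replicate 1, neither called.

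**Figure D4:**
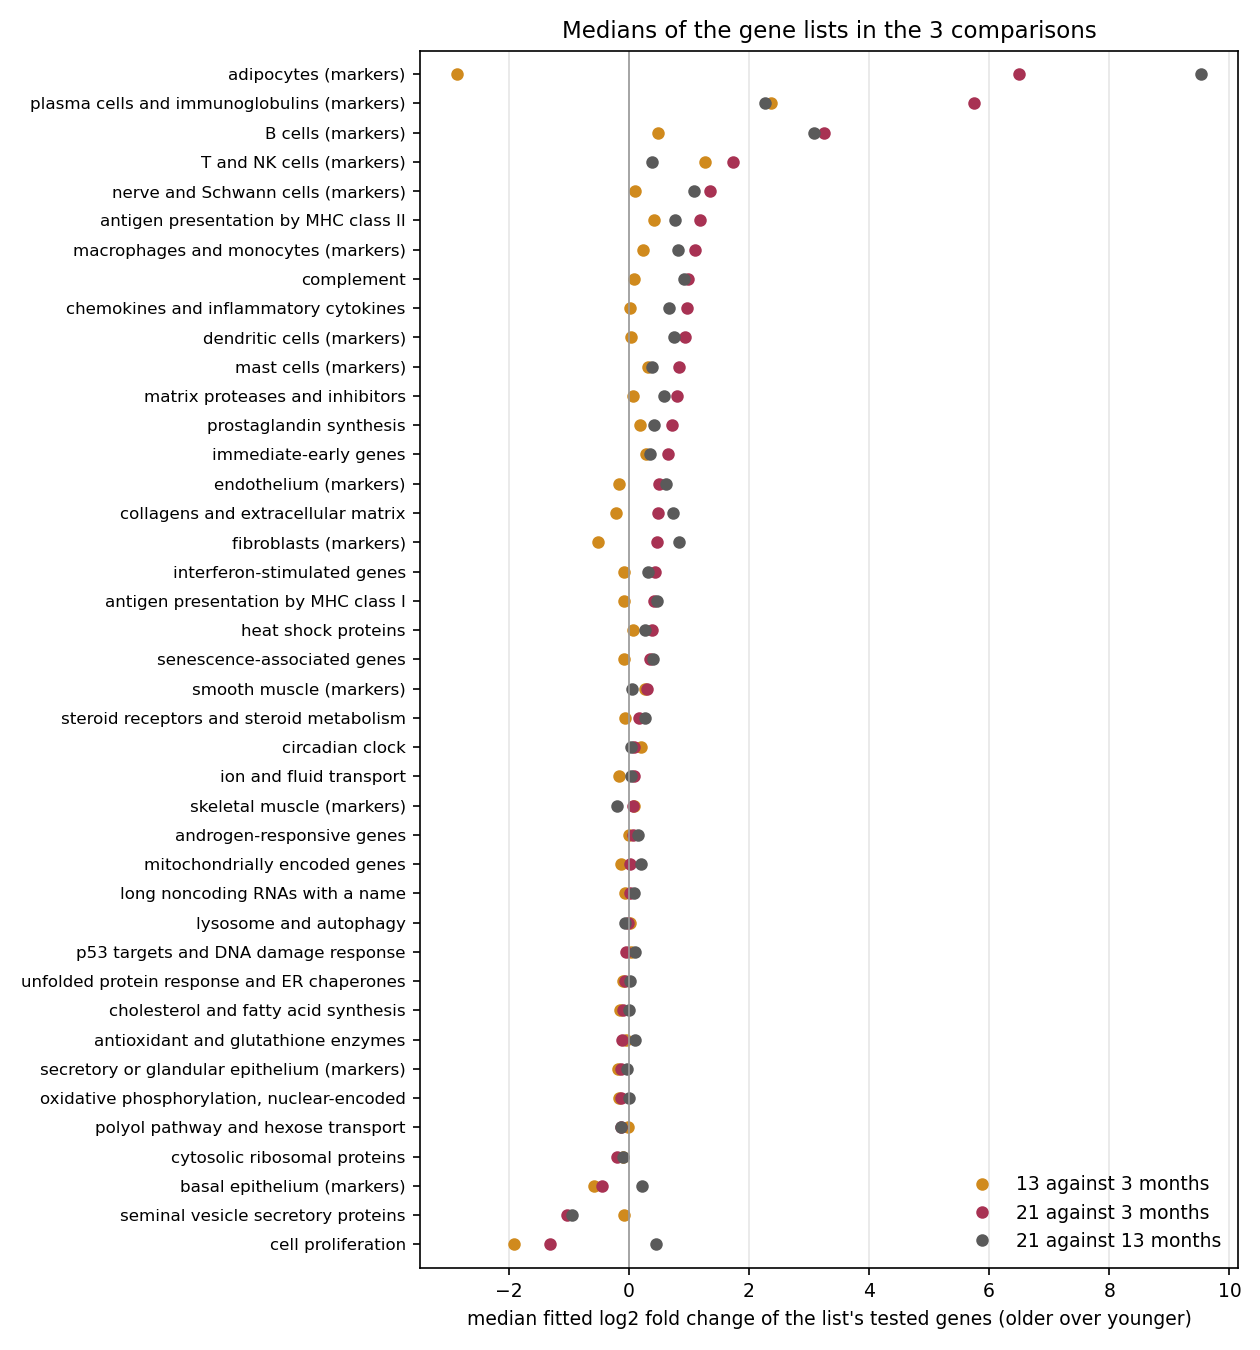
Median fitted log2 fold change, older over younger, of the tested genes of each of 41 lists in the 3 comparisons; each point is 1 list in 1 comparison. Cell proliferation is the lowest list called at 13 against 3 months (-1.92), and adipocyte markers are highest at 21 against 13 months (9.52), where 21-month replicates 1 and 2 carry the adipocyte transcripts, and scaling by library totals alone shifts the median gene by 0.609 at 21 against 3 months.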

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

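All tests in this part were chosen after the results were seen, except that of library depth for the proliferation genes, the counts of other splits of the libraries and the comparison of 21 with 13 months for Thbs1.

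In 21-month replicate 1, the genes reported here that were too sparse elsewhere to be tested and exceeded 300 CPM numbered 9. They were Tgm4 at 17560 (highest other library 0.524), Pbsn at 6317 (0.144), Tcaf3 at 4020 (0.202), Ren1 at 2153 (0.0605), 9530002B09Rik at 1116 (0), Mmp7 at 688.8 (0.844), C1s2 at 603.1 (0.385), Crisp1 at 420.4 (0.178) and Gm37223 at 364.9 (0.0481). An age change shared by all 21-month samples is argued against, since of the 9 prostate list genes over 50 CPM in replicate 1, 8 were at 5 times or more the highest of the 6 younger libraries there and 0 were in both replicates 2 and 3. Prostate tissue in the sample of replicate 1 is a candidate explanation, with 8 of 13 prostate list genes above 50 CPM there and below 1 in each other library. Fat tissue in the samples of replicates 1 and 2 is another, with 9 of 13 adipocyte list genes at 5 times or more the highest of the other 7 libraries in both. A change with age in the gland itself in single samples stays open and was not tested.

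The immunoglobulin transcripts that were higher at 21 months may come from plasma cells or from tissue and blood in the samples. Blood in the samples is argued against, since 4 haemoglobin genes had a median log2 fold change of 0.492 and a highest of 0.592 between 3 and 21 months, against 5.75 for the plasma cell list. All 4 older libraries with neither tissue lay above the highest 3-month library (0.00128%) in immunoglobulin share. Among them only replicate 3, at 0.0358%, is of 21 months, and the 13-month libraries lay between 0.00233% and 0.00679%. At 21 months carried-in prostate or fat as the whole cause is therefore argued against by that single library alone. Carried-in tissue as part of the rise in 21-month replicates 1 and 2 and a change with age, which the design names, stay open.

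Cell proliferation genes were lower at 13 months. With every library thinned to the smallest total, the list median was -1.86 and 17 members were called lower. The fall therefore did not need the extra counts of the deeper libraries. Totals at 3 and 13 months ran only from 16536160 to 24791943, and the fold changes were already scaled by library size. Thinning could hardly have changed the median much, so that this test cannot decide on library depth. The secretory epithelium markers had a median of -0.184 (quartiles -0.317 to 0.0544), a small fall called by camera with the preset correlation (adjusted p = 0.0493). That call ended under 7 of its 18 alternatives, which include leaving out any 1 of the 6 libraries compared. The median stayed between -0.205 and -0.114. Loss of secretory epithelium as large as the proliferation change is argued against, except for a loss shared by most genes, which TMM would remove. The choice among 4 scalings made little difference, with a highest median of the proliferation list of -1.86. These scalings moved the median of all genes at 13 against 3 months by 0.064 at most. The outcome could therefore hardly have differed, and it says nothing on an error that the 4 scalings share. A lower share of basal cells or of fibroblasts may contribute, with medians of -0.58 (quartiles -0.943 to -0.0801) and -0.51 (-0.772 to -0.206) beside -1.92 for the proliferation list. Age stays open as untested.

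Thbs1 changed more by 21 than by 13 months, each against 3 months, by 2.10 on the log2 scale (adjusted p = 0.0159 for the difference in edgeR).

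Other splits of the libraries into groups of the same sizes were fitted in the same way. For the genes that differed across the 3 ages, 100 splits were fitted, the real one and a random draw of the others. Only the real one, with 144, called as many, and the highest other called 87. A share under 0.05 argues against a chance assignment of libraries to ages but does not exclude it. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 73 genes between 3 and 13 months and 325 between 3 and 21 months, the largest in 1 of 10 splits each, with 0 in the highest other in edgeR. Between 13 and 21 months it called 1, reached in 2 of 10 splits, with 3 in the highest other. For lists the real values were 12, 19 and 24, reached in 3, 2 and 1 of 10 splits, with 12, 21 and 21 in the highest other.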

How the results depend on the processing

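The tests with 21 months as replicate 3 alone and with a robust spread were chosen after seeing the data. Of the named genes called, 18, 58 and 1 at 13 against 3, 21 against 3 and 21 against 13 months, none held under every alternative, while 12, 16 and 0 held under every alternative with all libraries, and 0 reversed. Of the lists called, 12, 19 and 24, 3, 9 and 13 held under every alternative other than the estimated correlation and fry. The cause of these differences was not tested.

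The genes changed between 3 and 13 months numbered 33 with at least 10 counts in all 9 libraries, 211 by DESeq2, 235 with only the 6 libraries of the 2 ages compared, 45 with a replicate block, 229 with 21 months as replicate 3 alone, and 1 to 150 leaving out 1 library. The genes changed between 3 and 21 months numbered 69 with at least 10 counts in all 9 libraries, 1503 by DESeq2, 728 with every gene with at least 1 count, 5695 with library totals alone, 154 by limma-voom, 112 with only the 6 libraries, 57 with replicate 3 alone, and 0 to 2349 leaving out 1 library. The genes changed between 13 and 21 months numbered 428 by DESeq2, 5 with every gene with at least 1 count, 1240 with library totals alone, 3 by limma-voom, 3 with a replicate block, 0 with only the 6 libraries in edgeR (1687 at an unadjusted p under 0.05), and 0 to 1244 leaving out 1 library. The genes changed across the 3 ages numbered 43 with at least 10 counts in all 9 libraries, 1357 by DESeq2, 697 with every gene with at least 1 count, 3723 with library totals alone, 73 by limma-voom, and 3 to 1639 leaving out 1 library. The overlap of changes at 13 and 21 months was 162 by DESeq2, 33 with replicate 3 alone, and 0 to 90 leaving out 1 library.

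The gene lists called between 3 and 13 months, 3 and 21 months, and 13 and 21 months numbered 1, 0 and 0 by camera with an estimated correlation and 1, 8 and 2 by fry, and the first 7 to 14 leaving out 1 library. With 21 months as replicate 3 alone the median of the list of markers of adipocytes was -3.20 at 21 against 3 months and -0.59 at 21 against 13 months. The adipocyte share at 3 months was 0.00449% in replicate 2, against 0.00167% and 0.0021% in replicates 1 and 3. Cfd stood at 7.983 CPM in that replicate against 0.05 and 0.12, while Plin4 differed less (13.788 against 9.861 and 13.366). The -3.20 therefore leans on 3-month replicate 2 and does not show a fall with age. At 21 against 13 months the list of heat shock proteins then stood at -0.084 and markers of secretory or glandular epithelium at 0.18. Markers of plasma cells and immunoglobulins stood at -0.036 there with at least 10 counts in all 9 libraries, a filter that removes genes absent at 3 months, and markers of smooth muscle ran from -0.21 to 0.24 leaving out 1 library.

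Whether the replicate numbers pair the samples is not settled by these values, and no test of it was made. Of 9 pairs of the same number 3 correlated above 0.1, over a range of -0.17 to 0.208. Of 9 libraries 5 lay closest to a library of their own number.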

Other observations

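The genes in this part and the tests on them were chosen after the values were seen. H60b (chromosome 10, 22158586 to 22288849), which encodes a ligand of the NKG2D receptor of NK cells, fell from 3.15 ± 0.759 CPM at 3 months to 0.317 ± 0.139 at 13 months (SD, n = 3; log2 -3.32 ± 0.49, adjusted p = 0.0221). By 21 months it fell by 4.05 (adjusted p = 0.0153). Raet1d, another gene of that ligand family, had a log2 difference of -2.39 that did not pass at 13 months (adjusted p = 0.142) and fell by 2.86 at 21 months (0.0426).

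On chromosome X the acyltransferase family gene Dgat2l6, the mitotic kinesin gene Kif4 and the phosphodiesterase gene Gdpd2 lie within 214.1 kb, and all 3 fell between 3 and 21 months. Kif4 fell by 2.31 (adjusted p = 0.0162). The last tested gene of the span, Pdzd11, had a log2 difference of -0.67 that did not pass (adjusted p = 0.0746). Of 503 tested genes on the chromosome 8 were lower at 21 months. No enrichment of the span was tested, since it was chosen for these genes. The genes changed between 3 and 13 months numbered 4, 1 and 9 without 3-month replicates 1, 2 and 3, and genes changed between 3 and 21 months 2, 4 and 0 in edgeR, the last with 3298 at an unadjusted p under 0.05.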
